A study of Zea mays with 12 samples.

How the data were processed

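RNA was measured in leaves of maize seedlings of the inbred line B73, taken as wild type, and of the mutant stock zmcryq, whose name refers to cryptochromes, the blue-light receptors of plants. Per the labels, the seedlings were 7 days old, were raised under white light and spent 48 h in the dark, after which they stayed in the dark or received blue light for 1 h. The labels do not say how the age relates to the dark period. There were 4 groups of 3 libraries, and the labels do not say that libraries of a group came from separate plants, so p-values measure only the spread between these 12 libraries, which may be technical. Total RNA was converted with an Illumina TruSeq kit, per the labels' protocols.

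The authors deposited 1 table of 44303 gene IDs with a value per library and 4 columns of group means, which were not used further. The deposited values were read as FPKM, fragments scaled by transcript length and by the mapped total of the library, although no header or label states the unit. The values carry decimals and add up to different totals in different libraries, and Cufflinks, which writes FPKM, is named in the submitters' processing notes; TPM over a larger set of genes is not excluded by the values. The submitters' processing notes also name Trimmomatic 0.36, HISAT2 2.2.1.0, TopHat, Bowtie2 and DESeq 1.18.0, with no role or order. The genome build, the annotation release, the use of strand and the treatment of fragments shared between copies of a gene are not given in the sources used here, so near-identical copies and overlapping genes cannot be told apart.

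The gene IDs have the form Zm00001eb followed by 6 digits. Of these IDs, 0 were found in the reference table of gene names, and the files do not pair IDs with names. Genes are therefore given by ID, at most 2 that rose and 2 that fell per comparison. Gene lists for light signalling, photosynthesis, pigment synthesis, clock genes and cell types had been fixed before the data were examined, and these list tests, as well as the cryptochrome genes themselves, were not analysed here because the lists are written as names. The knockout of the targeted genes was for the same reason not checked in these libraries.

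Genes at 1 FPKM or more in at least 3 libraries were tested, 21472 of the 44303. Of the rest, 11237 were listed at 0 in every library. A linear model with 1 mean per group was fitted to log2(FPKM + 1) of all 12 libraries with limma 3.58.1 in R 4.3.3, with trended and robust moderation and Benjamini-Hochberg adjustment, and genes under an adjusted p of 0.05 were called, in 2-sided tests. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Comparisons were blue against dark in each genotype, zmcryq against B73 in each light, and the difference of the blue responses, zmcryq minus B73. The design was fixed before the data were examined, with no scaling between libraries beyond FPKM, and scaling by median ratios had been listed with it as another setting. The scaled result is printed beside each count, because the libraries differed in scale within groups. Its factor for a library is the median ratio to the geometric mean over the 19555 tested genes above 0 in all libraries. This scaling sets the median change near 0 by construction, and a shift shared by most genes would be removed. Similar numbers of genes higher and lower after scaling therefore do not show a balanced response.

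The unscaled fit carried this scale difference in every gene. Its median residual SD was 0.494 on the log2 scale, against 0.18 after scaling, and the median of its prior degrees of freedom was infinite. Adjusted p-values are therefore printed from the scaled fit, whose median prior was 3.22 degrees of freedom beside 8 residual ones. The fits were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 21472. For the blue response of B73, 0% and 97% were recovered unscaled and 83% and 97% after scaling. For that of zmcryq the values were 32% and 60% unscaled and 84% and 97% after scaling. For the genotype difference in the dark they were 7% and 57% against 82% and 98%, in blue light 1% and 92% against 79% and 96%, and for the difference of responses 1% and 44% against 65% and 96%. The unscaled fit also made more false calls than its threshold states: unchanged genes were 31.2% of its calls for the blue response of B73, 46.8% for that of zmcryq, 46.7% for the genotypes in the dark, 31.1% in blue light and 58.7% for the difference of responses. After scaling they were 2.17%, 3.72%, 6.25%, 4.89% and 3.59%. These shares hold for 200 changed genes, as many raised as lowered. The simulated libraries were built from the scaled means and spreads and multiplied by the same factors, which favours the scaled fit by construction. In the real data, 52.1% of tested genes were called after scaling for the blue response of B73 and 56.2% for that of zmcryq. So many changed genes were not simulated, so the shares do not bound the false calls among the real counts.

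Absolute depth is unknown in FPKM, and no counting interval is given. Low values fall in steps of what 1 fragment is worth, and ratios of these steps between libraries, taken over values of 0.1 to 0.6 FPKM, gave relative mapped totals. These are mapped totals only if the values are FPKM. Of 66 library pairs, 63 lay within 0.1 log2 of the fitted ratios. No pair of libraries shared more than 1.75% equal values above 0, so none was a repeated deposit.

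Named genes followed a rule fixed before the data were examined: called genes with group values that do not overlap (not required for the difference of responses) and at least 5 FPKM in the higher group, ranked by fold change. The part of the rule that asks for an informative name could not be applied, and 2 genes per direction were taken. Other alternatives were quantile normalization, pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, array weights, moderation without trend, the replicate number as a block, fits of 6 libraries, each library left out, a 2-fold minimum and an adjusted p of 0.01. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.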

Results

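Leaf RNA was profiled in 4 groups of 3 libraries: B73 in the dark, B73 after 1 h of blue light, zmcryq in the dark and zmcryq after 1 h of blue light. The comparisons ask how leaf gene expression responds to blue light, and how the response and the starting state differ in the mutant. The totals per library ran from 588717 FPKM in B73 blue replicate 2 to 814802 FPKM in zmcryq blue replicate 3. The 20 most abundant genes, picked once by their mean over all 12 libraries, took 10.1% of the total in B73 blue replicate 3. They took 39.4% in zmcryq dark replicate 1. The median-ratio factors ran from 0.507 in zmcryq dark replicate 1 to 1.64 in zmcryq blue replicate 3, a 3.24-fold range. Libraries of a group correlated at 0.95 to 0.984 across genes, which are not independent replicates.

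**Figure D1:**
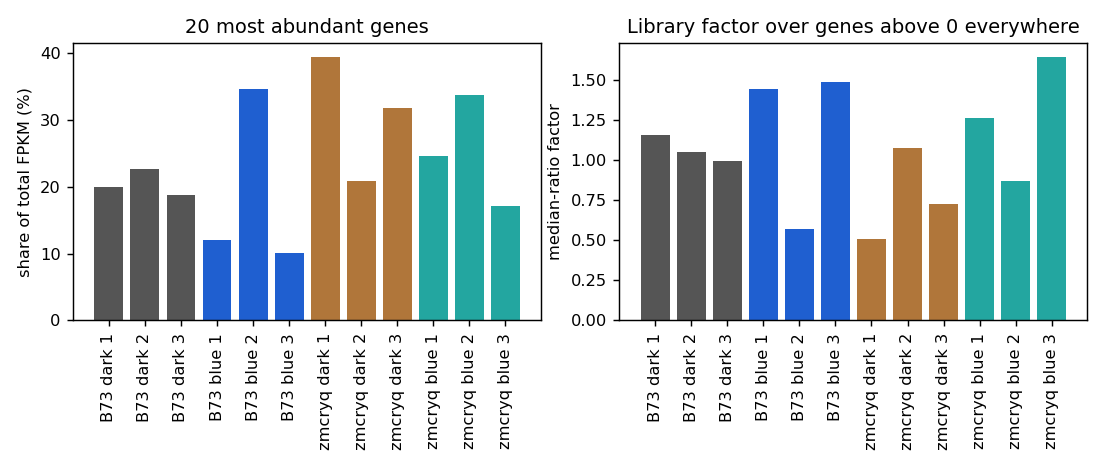
Share of total FPKM in the 20 genes with the highest mean over all libraries (left, percent) and median-ratio factor (right, no unit). Each of the 12 libraries has 1 bar, with colours for the groups. B73 blue replicate 2, with a share of 34.6%, had a factor of 0.567, and B73 blue replicate 3, with 10.1%, had a factor of 1.49.

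After scaling, both genotype and light separated the libraries. On the first principal component, with 48.6% of the variance, mean scores were 91.8 ± 2.88 (SD, n = 3) for zmcryq dark, 34.3 ± 4.52 for zmcryq blue, -22.6 ± 1.48 for B73 dark and -104 ± 3.3 for B73 blue. On the second, with 30.7%, they were -23.3 ± 4.84 for zmcryq dark, 78.4 ± 3.16 for zmcryq blue, -77.3 ± 1.61 for B73 dark and 22.1 ± 1.47 for B73 blue. The differences between the groups exceeded the spread within them on both components. In the unscaled values this did not hold: B73 blue replicate 2 scored -20.7 and -56.6 on the first and second components, near the B73 dark libraries (-23.3 to -5.8 and -75.7 to -59.4), while B73 blue replicates 1 and 3 scored -129 and -134 on the first.

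**Figure D2:**
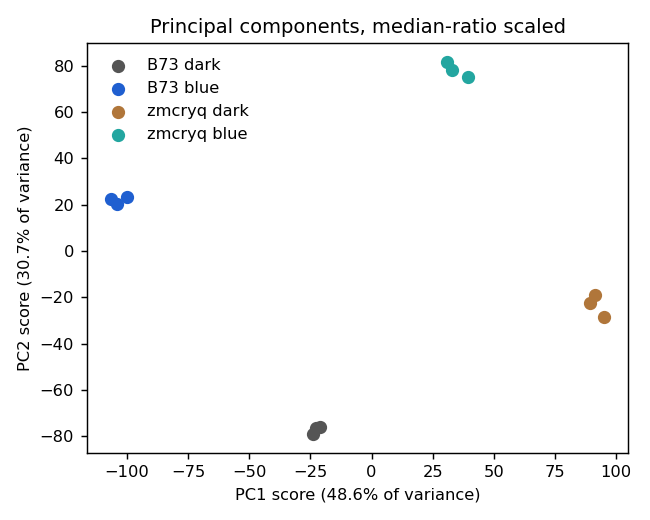
Scores of the 12 libraries on the first and second principal components of median-ratio scaled log2(FPKM + 1) values, with 1 point per library coloured by group. The first component holds 48.6% and the second 30.7% of the variance, and each group of 3 stands apart.

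In B73, 1 h of blue light raised Zm00001eb149430 from 10.2 ± 1.67 FPKM to 3750 ± 1830 FPKM (SD, n = 3 each). Zm00001eb258360 rose from 0.17 ± 0.0436 to 305 ± 155 FPKM. Zm00001eb283070 fell from 157 ± 52 to 2.93 ± 1.13 FPKM, and Zm00001eb261620 from 439 ± 94.5 to 12.6 ± 5.28 FPKM.

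The log2 change of Zm00001eb149430 was 8.25 ± 0.48 (SE) unscaled and 8.24 ± 0.16 after scaling (limma adjusted p 5.6e-11). Zm00001eb258360 changed by 7.88 ± 0.42 and 7.8 ± 0.17 (limma adjusted p 6.6e-11). Zm00001eb283070 changed by -5.32 ± 0.49 and -5.32 ± 0.18 (limma adjusted p 1.4e-09), and Zm00001eb261620 changed by -5.08 ± 0.51 and -5.09 ± 0.38 (limma adjusted p 1.3e-06). Blue light raised 2152 genes and lowered 1523 in the unscaled fit, 58.6% of the called genes being higher. After scaling 5774 rose and 5416 fell, 51.6% higher, and with a minimum of 2-fold 2140 rose and 1764 fell, against 1951 and 1381 unscaled. Of the 3675 unscaled calls, 3584 were called in the same direction after scaling and 0 in the opposite direction. The number of genes raised rested on single libraries in the unscaled fit: it was 5009 without B73 blue replicate 2, 1433 without B73 blue replicate 1 and 1412 without B73 blue replicate 3.

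In zmcryq, blue light raised Zm00001eb164860 from 0.247 ± 0.0929 to 109 ± 56.4 FPKM and Zm00001eb247760 from 0.667 ± 0.169 to 93.3 ± 53.8 FPKM (SD, n = 3 each). Zm00001eb012240 fell from 202 ± 64.7 to 5.14 ± 1.75 FPKM and Zm00001eb221090 from 71.4 ± 36.5 to 1.09 ± 0.146 FPKM. These 4 genes moved the same way in B73: Zm00001eb164860 went from 2.7 ± 0.669 to 49.3 ± 20.4 FPKM there, Zm00001eb247760 from 5.49 ± 0.807 to 65.3 ± 25.7, Zm00001eb012240 from 97.4 ± 22.1 to 6.92 ± 6.73 and Zm00001eb221090 from 156 ± 30.7 to 9.21 ± 5.14.

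The log2 change of Zm00001eb164860 in zmcryq was 6.31 ± 0.45 (SE) unscaled and 5.92 ± 0.21 after scaling (limma adjusted p 1.3e-08). Zm00001eb247760 changed by 5.65 ± 0.46 and 5.18 ± 0.19 (limma adjusted p 1.3e-08). Zm00001eb012240 changed by -5.03 ± 0.48 and -5.69 ± 0.46 (limma adjusted p 4e-06), and Zm00001eb221090 changed by -4.97 ± 0.47 and -5.53 ± 0.35 (limma adjusted p 5e-07). In zmcryq blue light raised 5576 genes and lowered 912 unscaled, 85.9% of calls being higher, but the median of all tested genes was itself shifted by 0.56 on the log2 scale. After scaling, which sets the median near 0 by construction, it was 0.01. Then 6087 genes rose and 5971 fell, 50.5% higher, with 1809 and 2186 at 2-fold or more. Whether most genes shifted together cannot be told from these values. Of the 6488 unscaled calls, 6024 were called in the same direction after scaling and 0 in the opposite direction. The 5576 genes raised became 8409 without B73 blue replicate 2, 2541 without zmcryq dark replicate 1, 3298 without zmcryq dark replicate 3, 3107 without zmcryq blue replicate 1 and 2564 without zmcryq blue replicate 3.

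In the dark, before any blue light, Zm00001eb347080 was listed at 147.65, 288.44 and 199.75 FPKM in the zmcryq libraries and at 0 in all 3 B73 libraries. Zm00001eb324290 was listed at 127.2, 280.86 and 220.4 FPKM in zmcryq and at 0, 0 and 0.05 in B73. In the other direction, Zm00001eb270140 stood at 283 ± 38.8 FPKM in B73 and 0.217 ± 0.0777 in zmcryq (SD, n = 3 each), and Zm00001eb202230 at 221 ± 22.1 and 0.113 ± 0.0929 FPKM.

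For Zm00001eb270140 the log2 difference, zmcryq minus B73, was -7.86 ± 0.45 (SE) unscaled and -7.7 ± 0.14 after scaling (limma adjusted p 6.4e-12), and for Zm00001eb202230 it was -7.64 ± 0.44 and -7.52 ± 0.1 (limma adjusted p 5.1e-13). Unscaled, 971 genes were higher and 3106 lower in zmcryq, 23.8% higher, with the median of all tested genes at -0.38. After scaling, which sets the median near 0 by construction, it was 0.03. Then 5384 genes were higher and 5298 lower, 50.4% higher, with 1605 and 1866 at 2-fold or more. Of the 4077 unscaled calls, 3947 were called in the same direction after scaling and 0 in the opposite direction. The 3106 genes lower became 5113 without B73 blue replicate 2, 1868 without B73 dark replicate 1, 2024 without B73 dark replicate 2, 1730 without zmcryq dark replicate 1 and 1913 without zmcryq dark replicate 3.

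Under blue light, Zm00001eb213310 was listed at 439.28, 323.82 and 702.53 FPKM in zmcryq and at 0 in all 3 B73 libraries. In the dark it was already listed at 22.34, 48.06 and 28.73 FPKM in zmcryq and at 0 in all 3 B73 libraries. Zm00001eb324290, also higher in the dark, was listed at 297.98, 203.72 and 349.27 FPKM in zmcryq and at 0.25, 0 and 0.12 in B73. Zm00001eb149430, the gene with the highest rise named for B73, stood at 3750 ± 1830 FPKM in B73 and 7.26 ± 3.72 in zmcryq (SD, n = 3 each). Zm00001eb146510 stood at 722 ± 330 FPKM in B73 and 2.77 ± 1.34 in zmcryq.

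For Zm00001eb149430 the log2 difference under blue light, zmcryq minus B73, was -8.77 ± 0.48 (SE) unscaled and -8.93 ± 0.16 after scaling (limma adjusted p 6.3e-12), and for Zm00001eb146510 it was -7.51 ± 0.46 and -7.62 ± 0.14 (limma adjusted p 5.5e-12). Unscaled, 2492 genes were higher and 2372 lower in zmcryq, 51.2% higher, with the median of all tested genes at 0.17. After scaling 5773 were higher and 6030 lower, 48.9% higher, with 1910 and 2715 at 2-fold or more. Of the 4864 unscaled calls, 4726 were called in the same direction after scaling and 0 in the opposite direction. The 2372 genes lower became 4251 without B73 blue replicate 2, and the 2492 higher became 1640 without zmcryq blue replicate 3.

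After scaling, genes raised by blue light in B73 tended to rise less in zmcryq. Of the 2140 genes raised 2-fold or more in B73 after scaling, 1421 also rose in zmcryq (66.4%; 606.7 for independent lists), 93 fell and 626 were not called there. The test of the difference itself called a smaller response in zmcryq for 1254 of the 2140 (58.6%) and a larger one for 86, and the median log2 change was 1.53 in B73 and 0.74 in zmcryq. Of the 1764 genes lowered 2-fold or more in B73, 1500 fell in zmcryq (85%), and the difference test called 448 as weaker (25.4%) and 165 as stronger. Genes picked for a large change in one set of libraries regress towards a smaller one in another, so the reverse selection gives the scale: of 1809 genes raised 2-fold or more in zmcryq, 650 were called weaker in B73 (35.9%), and of 2186 lowered, 769 (35.2%). Unscaled, of 1951 genes raised 2-fold or more in B73, 361 were called weaker in zmcryq (18.5%) and 35 stronger. In the reverse selection, of 4846 raised in zmcryq, 382 were called weaker in B73 (7.88%) and 53 stronger. For genes raised in zmcryq, the median log2 change after scaling was 1.32 in zmcryq and 0.89 in B73. Unscaled it was 1.41 in zmcryq and 0.59 in B73, against 1.65 in B73 and 1.21 in zmcryq for genes raised in B73. By medians, the larger drop was thus in the genes picked in B73 after scaling, but in those picked in zmcryq unscaled.

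**Figure D3:**
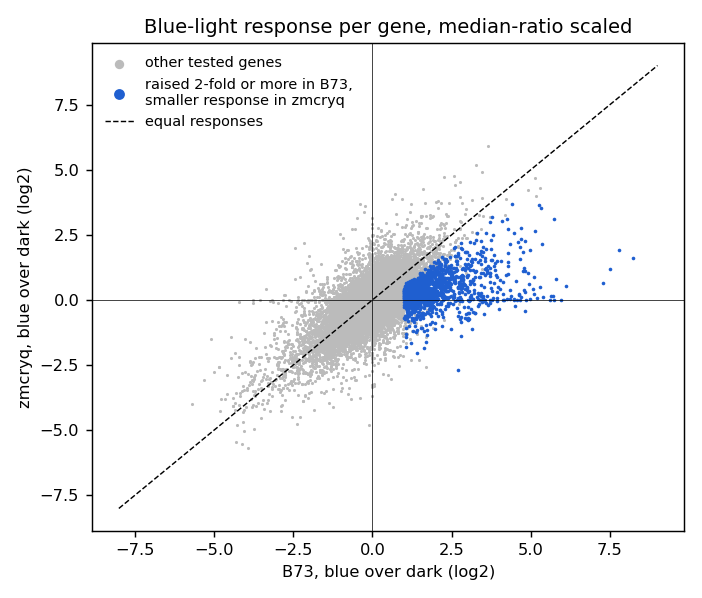
Log2 blue over dark change of each tested gene in B73 (horizontal) and in zmcryq (vertical) after median-ratio scaling, with 1 point per gene and a dashed line of equal responses. The coloured points are the 1254 genes raised 2-fold or more in B73 whose response was called smaller in zmcryq.

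Zm00001eb235510 went from 0.347 ± 0.28 to 236 ± 104 FPKM in B73 and from 0.17 ± 0.118 to 1.21 ± 0.662 in zmcryq (SD, n = 3 each), and Zm00001eb149430 from 10.2 ± 1.67 to 3750 ± 1830 in B73 and from 0.947 ± 0.587 to 7.26 ± 3.72 in zmcryq. Zm00001eb072670 was listed at 4.92, 3.03 and 3.22 FPKM in B73 dark and at 0 in all 3 B73 blue libraries, while in zmcryq it was listed at 0 in all 3 dark libraries and at 2.54, 2.32 and 12.82 in blue. Zm00001eb368220 was listed at 0, 0 and 1.74 FPKM in zmcryq dark and at 20.63, 15.79 and 29.83 in zmcryq blue, with 4.52, 2.07 and 6.84 in B73 dark and 9.72, 4.58 and 0 in B73 blue.

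The difference of log2 responses, zmcryq minus B73, was -6.48 ± 0.57 (SE) unscaled and -6.62 ± 0.22 after scaling for Zm00001eb235510 (limma adjusted p 1.1e-08), and -6.21 ± 0.68 and -6.63 ± 0.23 for Zm00001eb149430 (limma adjusted p 1.1e-08). It was 4.38 ± 0.66 unscaled and 3.86 ± 1.15 after scaling for Zm00001eb368220 (limma adjusted p 0.035). That call was lost unscaled without B73 blue replicate 2 (limma adjusted p 0.12), with no filter (0.083), with a pseudocount of 0.1 (0.19) and without both libraries of lowest factor, zmcryq dark replicate 1 and B73 blue replicate 2, a repeat chosen after seeing the data (0.22). After scaling, in repeats also chosen then, it was lost with the replicate block (limma adjusted p 0.075), with a pseudocount of 0.1 (0.065) and without B73 dark replicate 1 (0.069) or 3 (0.076), zmcryq dark replicate 1 (0.077) or 2 (0.074), or zmcryq blue replicate 1 (0.065), 2 (0.065) or 3 (0.064). For Zm00001eb072670 the difference was 4.67 ± 0.44 unscaled and 4.35 ± 0.44 after scaling (limma adjusted p 3.8e-05), a size that depended on the pseudocount: unscaled it was 10.67 with a pseudocount of 0.1 and 1.79 with 5. For Zm00001eb368220 these values were 7.65 and 2.32, and 2.01 with array weights. Unscaled, the response was called higher in zmcryq for 605 genes and lower for 412, 59.5% higher, with the median of all genes at 0.56. After scaling it was called higher for 2322 and lower for 3221, 41.9% higher, with the median at -0.01, and at 2-fold or more for 771 and 1581. Quantile normalization gave 3207 higher and 2856 lower, with more genes higher as in the unscaled fit. Unscaled, more genes were lower without B73 blue replicate 2 (633 higher and 835 lower), zmcryq dark replicate 1 (336 and 415) or zmcryq blue replicate 3 (346 and 423), so the balance of the 2 directions is not settled. Of the 1017 unscaled calls, 914 were called in the same direction after scaling and 0 in the opposite direction. The 605 became 343 without B73 dark replicate 1, 357 without B73 dark replicate 2, 336 without zmcryq dark replicate 1, 357 without zmcryq dark replicate 3, 367 without zmcryq blue replicate 1 and 346 without zmcryq blue replicate 3, and the 412 became 835 without B73 blue replicate 2.

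**Figure D4:**
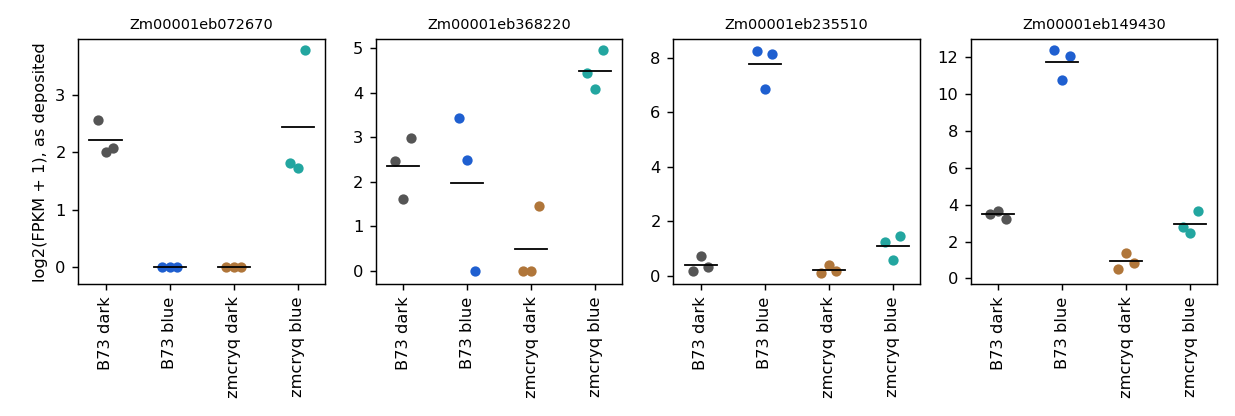
Deposited values on the log2(FPKM + 1) scale of the 4 genes named for the difference of blue responses, with 1 point per library, a bar at the mean of each group of 3 and 1 panel per gene. Zm00001eb235510 and Zm00001eb149430 rose further in B73 than in zmcryq, while Zm00001eb072670 was listed at 0 in B73 blue and in zmcryq dark.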

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

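The tests of the library factors and of the genes listed in a single genotype, and the repeats named as such, were chosen only after the results were seen. The difference between the genotypes in blue response was picked out by its own test: unscaled it was higher in zmcryq for 605 genes and lower for 412. The genes named from it differed by 4.67 (Zm00001eb072670), 4.38 (Zm00001eb368220), -6.48 (Zm00001eb235510) and -6.21 (Zm00001eb149430) on the log2(FPKM + 1) scale. The first pair has libraries at 0, and its sizes depend on the pseudocount: with 0.1 and 5 in place of 1 they were 10.67 and 1.79 for Zm00001eb072670 and 7.65 and 2.32 for Zm00001eb368220, which had 2.01 with array weights.

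Among 100 groupings of the 12 libraries into 4 groups of 3, after removal of additive effects, 5 gave at least the 572 unscaled calls of the real grouping, so chance is not excluded for the unscaled count by the test as planned. The highest other grouping gave 13502, which points to a structure of the samples: it was the grouping with the largest difference in library factors. After scaling 3 of 100 reached the real 5575, with 7342 the highest other, and both other groupings made the same contrast as the real one. A repeat that left out such equivalent groupings, written after these counts were seen, gave 2 of 100 unscaled (highest other 14254) and 1 of 100 after scaling (highest other 7). After scaling, no grouping with another contrast reached the real count in either form, which argues against a chance assignment of these 12 libraries. Unscaled, chance is not excluded: another grouping gave far more calls than the real one in both forms. The later form was also written after the planned one had failed. All these shares treat the 12 libraries as exchangeable, and they do not bear on other plants if libraries of a group are technical repeats.

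Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05, and in each the real split, 1 of 10, called the most genes. For blue light in B73 it called 3675 unscaled and 11190 scaled, with 11 and 2 the highest other, and for blue light in zmcryq 6488 and 12058, with 26 and 3. For the genotypes in the dark it called 4077 and 10682, with 9 and 4 the highest other, and in blue light 4864 and 11803, with 2 and 1.

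Library factors differed within groups, up to 2.62-fold in B73 blue. An account in which a few abundant genes take a varying share of each library was first tested over all 4 groups, and the library with the highest share in its 20 most abundant genes had the lowest factor in 3 of 4; B73 dark, with factors 1.16-fold apart, went against it, and in that form the test argued against the account. Narrowed afterwards to the 3 groups with factors over 1.5-fold apart, the share was at least 1.89 times as high in the lowest-factor library, which leaves this account open for those 3 groups, as a hypothesis. Whether it covers the whole gap is not shown: by these shares the FPKM left to all other genes would differ only 1.37-fold in B73 blue, 1.31-fold in zmcryq dark and 1.25-fold in zmcryq blue, or 1.86-, 1.56- and 1.58-fold with the totals included, against factors 2.62-, 2.12- and 1.89-fold apart. Gene lengths are not given, so the share of fragments these genes took is unknown. In these 3 groups the lowest-factor library had at least 1.56 times the mapped total of the highest-factor library. Fewer mapped fragments are argued against there only if values are FPKM and the commonest ratio of low values is that of 1 fragment. At that ratio lay 83 of the 1644 genes low in both B73 blue replicates 2 and 3. The ratios of mapped totals were 1.86, 1.56 and 1.58, as for the FPKM with the totals included, so the 2 may not be separate evidence. Over all 4 groups the lowest ratio was 1, in B73 dark. No biological explanation was tested, since the differences lie within groups.

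By a rule set after the values were seen, 245 genes were listed in a single genotype in both lights, at 1 FPKM or more in all 6 libraries and at most 0.1 in the other 6: 152 in zmcryq and 93 in B73. A counting floor is argued against only for the 64.1% with a median of 5 FPKM or more where present. The rule asks for 1 FPKM in all 6 libraries, which raises this share by itself. With presence at 5 FPKM, 86 genes were listed, 0.815% of 10546 eligible genes, against 1.41% of 17381 at 1 FPKM. Listing was thus commoner among lower genes, and a floor stays open for those. Only 2 other genes were listed in a single light by the same rule, which decides nothing about light signalling in the 245, picked for being listed in both lights. The rule written for this count would have read it as evidence against light signalling; that reading was given up after the value was seen. Alleles of a different strain background in blocks of the genome may account for part of the 245. With 1 gene kept per 20 IDs, 210 genes, the dispersion over windows of 400 IDs was 1.24 (permutation p 0.038). A comparison set of 158 genes, picked for the smallest p of the blue response of B73 and thinned alike, gave 0.949 (permutation p 0.61). Before thinning the values were 1.63 (permutation p 1e-04) for the 245 and 1.17 (permutation p 0.093) for 179 comparison genes. The comparison set was smaller, so its test had less power. Loss of the cryptochromes in either light stays open for all 245, since the design has 1 mutant stock and 1 wild type and mutation and stock cannot be told apart.

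Of the 2140 genes raised 2-fold or more in B73 after scaling, 1254 rose less in zmcryq. Of these 1254, 454 differed by more than 1.7, the log2 range of all library factors. By the rule written beforehand this is evidence against library scale as the whole cause. The range is no bound, because the differences come from values already divided by these factors and contrast group means. Unscaled, 361 of 1951 genes raised 2-fold or more in B73 were called weaker (18.5%). Some were thus called without scaling, but the number depends on it. Silence in zmcryq is argued against as the cause for all of these genes: 79% had a dark level within 2-fold of that in B73. Low genes pass this measure easily. Of the rest, more lay lower in zmcryq (15.8%) than higher (5.18%). In a repeat written afterwards, 71.7% reached 1 FPKM in every zmcryq blue library. Neither share was set against that of all tested genes, and silence stays open for part of the genes. For strain variants in blocks, the share of genes with a smaller rise was 60.8% in ID windows with 3 or more of the 245 genes and 59.5% in windows with 0 (permutation p 0.36). The rule written beforehand would have read this as evidence against strain variants; that reading was given up after the value was seen, because the difference of 1.28 percentage points lies within the SD of 3.42 under shifted windows, which decides nothing. Strain background and loss of the cryptochromes therefore cannot be told apart here.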

How the results depend on the processing

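Among alternatives for the named genes, 897 values kept their direction and side of the threshold and 13 did not, all 13 for Zm00001eb368220, which kept its direction. Zm00001eb072670 gave no value at the filter of 5 FPKM. Among counts, 461 stayed within 1.5 times and 81 did not; except where fewer genes or libraries entered, the cause was not tested. Repeats on scaled values, and those for the genes listed in a single genotype, were chosen after seeing the data. Counts are given as higher and lower. With median-ratio scaling, blue light in B73 gave 5774 and 5416, lower in zmcryq 5971, the genotypes in the dark 5384 and 5298, in blue 5773 and 6030, and the difference of responses 2322 and 3221. Quantile normalization gave 5311 and 5745, lower in zmcryq 5591, 5230 and 5267, 6876 and 5491, and 3207 and 2856. Array weights, whose estimation did not converge on unscaled values, gave for the 5 comparisons 10923 and 3712, 16613 and 4311, 3354 and 13629, 6828 and 10150, and 10868 and 3927, or 4144 higher for the difference after scaling. A filter at 5 FPKM, which tests fewer genes, gave 1370 higher for blue light in B73, 515 higher for the genotypes in the dark, 1373 and 1571 in blue, and 304 and 220 for the difference. With no filter the difference had 344 higher, and without trend or robust moderation 277 and 221. At an adjusted p under 0.01, blue light in zmcryq gave 3246 and 604, the genotypes in the dark 1978 lower and the difference 320 higher. With only the 6 libraries compared, the genotypes in the dark gave 4977 lower. Without both libraries of lowest factor, zmcryq dark replicate 1 and B73 blue replicate 2, blue light gave 5697 higher in B73 and 1559 lower in zmcryq, the genotypes 1583 higher in the dark and 4737 lower in blue, and the difference 1105 lower, or 1450 higher after scaling. Leaving out 1 library at a time, blue light gave 1412 to 5009 higher in B73 and 2541 to 8409 in zmcryq, the genotypes 1730 to 5113 lower in the dark, 1640 to 2884 higher and 1757 to 4251 lower in blue, and the difference 336 to 884 higher and 315 to 835 lower; the scaled counts all stayed within 1.5 times. After scaling, the 1254 genes with a smaller rise in zmcryq ranged from 1126 to 1397 without 1 library, were 1089 without both libraries of lowest factor, and were 826 with a pseudocount of 5; there the 448 that fell became 269, and the 650 and 769 of zmcryq 299 and 498, while array weights made the 448 into 713. Genes listed in a single genotype numbered 57 in zmcryq and 29 in B73 with presence at 5 FPKM, 60 in B73 with absence at 0, and 241 and 176 with absence up to 0.5 FPKM. The replicate numbers showed no clear pairing of the libraries, although a shared batch is not excluded. Unscaled, 18 same-number pairs had deviations correlated at -0.37 to 0.42, 4 over 0.1, and 6 of 12 libraries correlated best with their own number. After scaling the correlations were -0.3 to 0.32, 4 over 0.1, and 5 of 12 libraries did so. With the replicate block, blue light in B73 gave 2018 and 1390, in zmcryq 4968 and 833, and the difference 514 and 396, and no count moved by over 1.5 times; Zm00001eb368220 lost its scaled call (limma adjusted p 0.075; 0.013 to 0.077 over its scaled alternatives). Gene lists fixed by name were not run. Absolute depth is unknown, and relative mapped totals spanned 1.93-fold.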

Other observations

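The genes listed in a single genotype included well-expressed ones, and part of them responded to light. Medians where present ran from 1.25 to 186 FPKM for the 152 zmcryq genes and from 1.34 to 115 FPKM for the 93 B73 genes. The direction in zmcryq depended on the scaling: of the 152, 32 rose and 4 fell in blue light unscaled, 20 rose and 81 fell after median-ratio scaling, and 19 rose and 74 fell after quantile normalization, the last chosen, like the unscaled count, after seeing the data. Of all tested genes, 26% rose and 4.25% fell unscaled in zmcryq, and 28.3% and 27.8% after median-ratio scaling. After quantile normalization these shares were 29.9% and 26%. Relative to all tested genes, the median log2 change of the 152 was lower under each scaling. It was 0.24 against 0.56 unscaled, -0.38 against 0.01 after median-ratio scaling and -0.36 against 0.03 after quantile normalization. Of the 93 in B73, 7 rose and 14 fell unscaled, 17 and 34 after median-ratio scaling, and 15 and 37 after quantile normalization. Of all tested genes in B73, 10% rose and 7.09% fell unscaled, 26.9% and 25.2% after median-ratio scaling, and 24.7% and 26.8% after quantile normalization. The 245 make up 1.41% of the 17381 genes at 1 FPKM or more in all libraries of a genotype, and of 462 splits of the libraries into 6 and 6 the highest other gave 2.

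The blue responses of the 2 genotypes, which share no libraries, correlated across genes at 0.63 unscaled and 0.65 scaled, and the genotype differences in dark and blue at 0.71 and 0.72; genes are not independent replicates.

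A hypothesis formed after seeing the data is that genes raised by blue light in B73 already lie lower in zmcryq in the dark. The covariance across genes of the B73 blue response and the dark genotype difference was -0.0333 after scaling, against 0.034 for simulated unchanged groups that share the B73 dark libraries, a difference of -0.0677. Of 5964 genes called in both comparisons, 2388 moved the same way and 3576 opposite ways, against 2784.1 and 2782.7 for independent lists. Unscaled, the covariance was 0.00303 against a simulated 0.094, a difference of -0.091. Of 862 genes called in both there, 403 moved the same way and 459 opposite ways, against 317.6 and 380.2 for independent lists. Independent lists are not the value for no change under either scaling. The comparisons share the B73 dark libraries, which by itself favours moves the same way. The correlation across genes was itself slight, -0.04 after scaling and 0 unscaled. The simulation drew noise for each gene separately. Unscaled, its spread also held the scale difference between libraries, which genes share, so the simulated covariance is too large. The unscaled difference of covariance therefore decides nothing. After scaling, both the difference of covariance and the counts of called genes have the sign of the hypothesis. The cause of this pattern was not tested.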
